A study of Homo sapiens with 8 samples.

How the data were processed

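RNA from 8 samples of HEK293 cells, 4 labelled TIP60 knock-out and 4 labelled control, had been made into stranded poly(A) TruSeq mRNA libraries and sequenced as 80 bp paired-end reads on a NextSeq 500. Cells had been grown with 2 mM GlutaMAX, and doxycycline at 1 µg/ml for 3 days was given to all. The values used were the raw counts per gene that the authors deposited, 1 table per library, with no normalisation. Each table also held the gene length in bases, per the file headers, which was the same in all 8 tables and was used only where stated. According to the submitters' processing notes, reads were counted with featureCounts on hg38. The aligner, the annotation release, the strand setting and any filters are not given in the sources used here, and reads shared between paralogs or overlapping genes may therefore have been counted or dropped. The values were checked to be whole numbers of at least 0 with a different total in each table.

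Of 28395 entries, 459 had no gene ID and were left out. They held 0.0284 to 0.0425% of the counts. The 27936 genes kept are identified by Entrez gene ID, and 27744 of them were given symbols and positions from a RefSeq annotation of GRCh38.p14. Exon overlaps between genes were measured on GENCODE v29, where some current symbols, the histone genes among them, were not found and were not assessed. Counts per library summed to 3723992 to 18841774. CPM in the text are scaled by TMM factors, and intervals of CPM ratios are exact 95% intervals of the counts that cover counting error only, since reads without molecular identifiers are not independent molecules. A group without any count was set to a floor of 3 counts over the group.

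Samples were grouped by the KO or control label and the guide number, giving 4 groups of 2. Genes were kept by filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 14455. The comparison of KO with control used edgeR 4.0.16 (quasi-likelihood F test, TMM) on all 8 libraries with a term for the guide number and 5 residual degrees of freedom. Comparisons within a guide, between guides, between the control lines and between the KO lines used contrasts in a model of the 4 group means with 4 residual degrees of freedom, so that pairs of 2 libraries borrow the spread of all groups. The biological coefficient of variation was 0.0473. P-values were adjusted by Benjamini-Hochberg over all tested genes, and an adjusted p under 0.05 was called. Single measures of 4 against 4 libraries were tested by exact permutation, two-sided. Agreement of the guides was taken as the overlap of calls beside that of independent lists and as correlation across genes.

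Gene lists, written before the data were examined, held 1082 entries, all of which matched an entry of the tables. They were: TIP60 complex, other lysine acetyltransferases, H2A.Z and its exchange factors, CDK inhibitors and pocket proteins, DNA replication and G1/S genes, G2/M and mitosis genes, DNA damage signalling and double-strand break repair, replication-dependent histone genes, cytosolic ribosomal proteins, MYC targets and ribosome biogenesis, oxidative phosphorylation, mitochondrially encoded genes, cholesterol biosynthesis, glycolysis and hypoxia genes, ATF4 and amino-acid stress response, endoplasmic reticulum chaperones, heat shock genes, NRF2 target genes, proteasome subunits, interferon-stimulated genes, NF-kB and secreted inflammatory genes, cell death genes, autophagy and lysosome genes, extracellular matrix and mesenchymal genes, immediate-early genes, neuronal genes, kidney and nephron-lineage genes, TGF-beta target genes, Wnt target genes, Notch target genes, HOX genes, and markers of leukocytes, fibroblasts, endothelium, epithelial carcinoma and hepatocytes. Lists with at least 3 measured members were tested with camera in limma 3.58.1 on voom values (preset correlation 0.01), again with an estimated correlation, and with fry, which called 27 of 36 lists. Some genes stand in more than 1 list, so lists are not independent.

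The rule for the genes named was fixed before the data were examined: KAT5; 14 fixed regulators (CDKN1A, CDKN2A, CDKN1C, CDKN2C, MDM2, H2AZ1, H2AZ2, MYC, E2F1, CCNB1, MKI67, EP400, TRRAP); the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and every KO library on the same side of the controls of its guide; up to 4 members per list with the smallest p; up to 5 genes for the guide difference and up to 3 each way for the control lines; and the most abundant member of each of the 5 other-cell-type lists. RNASEH2C and the cleavage-stage and germline genes were named after their values were seen. Of these, 1 fixed regulator, 1 gene list with its examples and 2 members of other lists are not reported here, although they stayed in every count and adjustment.

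Alternatives fixed in advance were DESeq2 size factors in edgeR, DESeq2 1.42.0, no filter, a stricter filter (CPM of at least 1 in at least 4 libraries), a robust fit, a replicate block, a block by guide and replicate number, no guide term, limma-voom, a test against a fold of 1.5, each library left out in turn, and, for the guide overlap, an unadjusted p under 0.01. The share of the 50 most abundant genes was also taken over the top 10 and top 500. Scaling by library totals alone and counts thinned to the smallest library were added after seeing the data. Every split of the 8 libraries into 4 and 4 (35 in all) was fitted with the guide term, except the split that follows the guide number, which was fitted without it.

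The code was tested on simulated negative binomial counts with a biological coefficient of variation of 0.05 and the observed depths. Among 13855 simulated genes, 63 had a 1.5-fold, 63 a 2-fold and 65 a 4-fold change. The KO against control fit in edgeR recovered 77.8%, 98.4% and 100% of them, and 8 of 184 calls were false. DESeq2 recovered 74.6%, 95.2% and 95.4%. The contrast within sgRNA1 recovered 68.3%, 95.2% and 93.8% with 14 of 178 calls false. The guide difference recovered 44.6%, 85.9% and 96.9% with 10 of 156 false, and the control line contrast 69.2%, 95.3% and 96.8% with 7 of 174 false. With no changed gene, 0 genes and 0 lists were called. The simulated genes were independent of each other, so the result for lists does not cover correlation between genes. Few simulated genes were changed, whereas 63.0% were called in the data. The scaling and the rate of false calls were therefore not tested for that case. Software was R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The reads were not used here.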

Results

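The data were gene counts from 8 RNA-seq libraries of HEK293, an immortalised line derived from human embryonic kidney cells. The labels name 4 libraries TIP60 knock-out (KO) and 4 control. TIP60 is the lysine acetyltransferase encoded by KAT5, the catalytic subunit of a chromatin complex that acetylates histones H4 and H2A and exchanges the variant H2A.Z. Each arm held 2 libraries labelled sgRNA1 and 2 labelled sgRNA2. A single guide RNA directs a nuclease to its target, and doxycycline at 1 µg/ml for 3 days induced the guides in all 8 samples. The targets of the guides in the control libraries were not given, and the genotype label of the KO libraries carried a further component, left unexplained, that the control label lacked. The stated purpose was to find genes expressed differently between KO and control cells. Gene counts per library summed to 16934074, 13325415, 18841774 and 15009961 in the KO arm and to 12641650, 3723992, 14601552 and 12478705 in the control arm, in the order of guide and replicate. The shallowest library, control sgRNA1 replicate 2, held 29.8% of the counts of the next control library in size.

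KO libraries contained transcripts of more genes than control libraries. At the depth of the shallowest library, 16489 to 16536 genes had a count in the KO libraries and 15380 to 15599 in the control libraries (exact permutation p = 0.0286, two-sided, n = 4 per arm, the smallest p this design allows). The 50 most abundant genes held 11.8% ± 0.117 (SD) of the counts in KO and 11.3% ± 0.754 in control libraries (exact permutation p = 0.171). The 10 most abundant held 5.45% and 5.10% (exact permutation p = 0.4) and the 500 most abundant 33.7% in both arms (exact permutation p = 1). Mitochondrially encoded genes held 2.07% ± 0.0638 and 2.30% ± 0.710 (exact permutation p = 0.543), with a range of 1.29 to 2.92% among the control libraries. Total counts were higher on average in KO than in control libraries, without passing the test (exact permutation p = 0.0571). The first principal component of log2 CPM, counts scaled to a common library size, carried 73.6% of the variance and parted the arms, and the second, with 10.9%, set the shallowest control library apart.

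**Figure D1:**
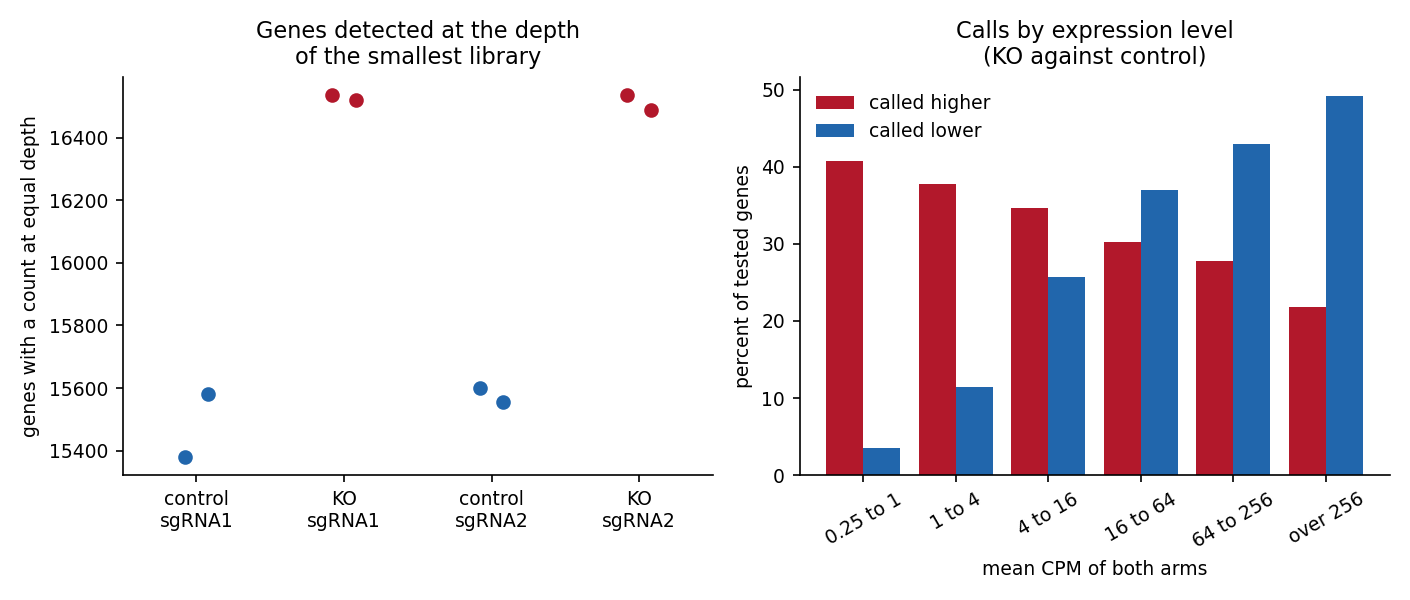
Left, genes with at least 1 count in each library at the depth of the smallest library, 1 point per library, where the 4 KO libraries lie between 16489 and 16536 and the control libraries between 15380 and 15599 (the axis does not start at 0). Right, percent of tested genes called higher or lower in KO by mean CPM of both arms, from 40.7% higher and 3.57% lower at 0.25 to 1 CPM to 21.9% and 49.2% in the most abundant class.

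KAT5 mRNA was reduced but still present in every KO library. KAT5 (gene ID 10524, chromosome 11, 65712018 to 65719604, GRCh38) had 18.5 ± 0.163 CPM (SD, n = 2) in KO sgRNA1 and 19.1 ± 1.54 in KO sgRNA2, against 46.8 ± 1.85 in control sgRNA1 and 46.8 ± 3.17 in control sgRNA2. The KO level was 40.1% of the control level, a log2 fold change of -1.32 ± 0.064 (SE, adjusted p = 6.71e-13), and the exact permutation p of the log2 CPM was 0.0286 (n = 4 per arm). With sgRNA1 the change was -1.36 ± 0.098 and with sgRNA2 -1.28 ± 0.088. RNASEH2C, the neighbouring gene for a subunit of ribonuclease H2, overlaps 38.6% of the annotated exonic bases of KAT5 on the other strand and itself fell (-0.33 ± 0.051), and the strand setting of the counting was not given.

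KO cells differed from control cells in the transcripts of most expressed genes, and most of the large changes were increases. Of the measured members, 24 of 27 histone genes and 25 of 27 immediate-early genes rose, as did the neuronal tubulin TUBB3 (log2 fold change 3.19 ± 0.068, SE), while 21 of 24 cholesterol synthesis genes and 33 of 40 MYC target and ribosome biogenesis genes fell by smaller amounts. Of 14455 genes tested, 4602 were higher and 4507 lower in KO at an adjusted p under 0.05, together 63.0% of genes. At least 2-fold changes were 1211 upward and 160 downward, and at least 4-fold changes 410 upward and 1 downward. With counts thinned to the smallest library, added after seeing the data, at least 2-fold changes were 695 upward and 168 downward among 12607 genes. The 1 gene at least 4-fold lower was SGIP1, an endocytic adaptor, whose change rested on the sgRNA1 controls. Among genes with a mean of 0.25 to 1 CPM, 433 of 1063 were higher and 38 lower, and in the most abundant class, 139 of 636 were higher and 313 lower. Of the 1211 genes at least 2-fold higher, 8 had no count and 43 had 1 to 3 counts in the control libraries. All p-values here measure only the spread between these libraries, since the labels do not say whether replicates were separate cultures, and without a spike-in a shift shared by all genes was not measurable. A test against a fold of 1.5 in place of no change called 1616 genes, 1216 higher and 400 lower.

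Among the 10 largest rises, values are log2 fold changes ± SE with every KO library above the controls of the same guide number. MYH8, a myosin heavy chain of perinatal skeletal muscle (chromosome 17, 10390322 to 10421950), had 9.89 ± 1.01 CPM (SD, n = 4) in KO libraries and no count in any control library, at least 141-fold higher when 3 counts over the control group are taken as the floor. FOXJ1, the regulator of motile cilia, had 254 KO counts and 2 control counts, a CPM ratio of 84.0 (95% counting interval 23.0 to 697). SCRT1, a neural transcriptional repressor, rose 39.4-fold by CPM ratio (17.9 to 108), LRRC15, a leucine-rich repeat membrane protein, 48.4-fold (18.7 to 179) and DGKK, a diacylglycerol kinase, 28.9-fold (14.5 to 67.6). MIR7-3HG, the host transcript of a microRNA, rose by 5.36 ± 0.31. The deubiquitinase-family genes USP17L7 (5.61 ± 0.26) and USP17L2 (4.84 ± 0.34) rose with LOC392196, beside them on chromosome 8, which had a CPM ratio of 89.3 (34.7 to 329), and RFPL4B rose 38.2-fold (14.7 to 141). USP17L and RFPL4 genes belong to multicopy families, so the copy that gave the reads is uncertain, and RFPL4B shares 36.7% of its exonic bases with another annotated gene on its strand. These intervals cover counting error only, and of the 6 control counts of SCRT1, 5 lay in control sgRNA2 replicate 2. Without that library the log2 fold change of SCRT1 was 7.04 in place of 5.18, and without control sgRNA1 replicate 2 that of RFPL4B was 5.90 in place of 5.11. Thinning, added after seeing the data, gave 5.81 for SCRT1 and 3.83 for RFPL4B, 7.32 for DGKK (4.79 unthinned), 7.94 for LOC392196 (6.30), 6.57 for USP17L7 (5.61), 4.65 for LRRC15 (5.45) and 8.27 for MYH8 (10.04). By limma-voom MYH8 had 7.56 and FOXJ1 5.42 (6.12 by edgeR), and by DESeq2 MYH8 had 8.999.

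The 10 largest falls were taken among called genes with a mean log2 CPM of at least 1 and the same order with each guide number. They were 2.57-fold to 3.25-fold and lay in genes of low to middle abundance. QRFPR, a neuropeptide receptor, fell most (-1.70 ± 0.20, 1.71 ± 0.592 CPM in KO against 5.44 ± 0.478 in control libraries, mean ± SD, n = 4), followed by the death receptor TNFRSF25 (-1.54 ± 0.23), the glycosyltransferase B4GALNT4 (-1.48 ± 0.077) and the nucleoside diphosphate kinase NME3 (-1.44 ± 0.076). HSBP1L1 (-1.44 ± 0.17), the antisense transcript H1-10-AS1 (-1.43 ± 0.13), the ERBB4 ligand NRG4 (-1.40 ± 0.16), the synaptic adhesion gene LRFN4 (-1.38 ± 0.072), the small nucleolar RNA host SNHG4 (-1.36 ± 0.10) and the Ras-like GTPase RASL10B (-1.36 ± 0.19) made up the rest. Thinned to the smallest library, added after seeing the data, RASL10B had -2.05. Exons of NRG4 overlap FBXO22 on the other strand over 38.1% of their bases, those of LRFN4 overlap PC over 22.0%, and those of SNHG4 overlap MATR3 on the same strand.

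**Figure D2:**
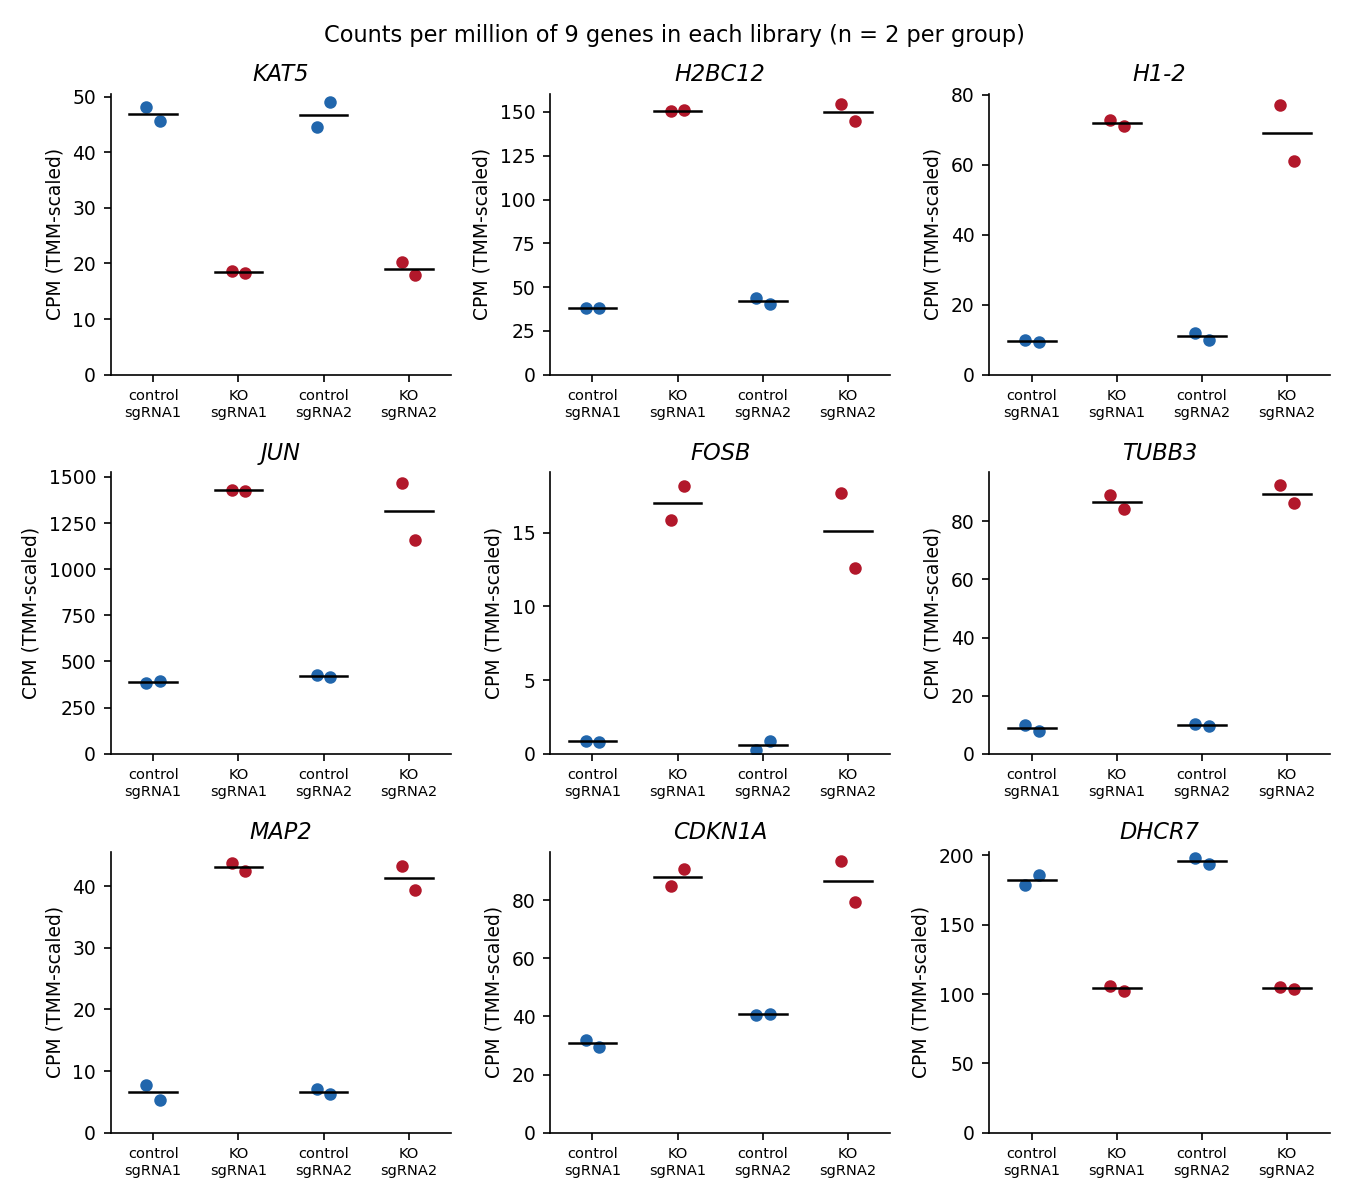
TMM-scaled CPM of 9 genes in each library, 1 point per library and a line at the group mean (n = 2 per group, axes from 0). KAT5 and DHCR7 are lower and H2BC12, H1-2, JUN, FOSB, TUBB3, MAP2 and CDKN1A higher in every KO library than in every control library.

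The fixed regulators of the cell cycle moved apart. The cyclin-dependent kinase (CDK) inhibitor CDKN1A (p21) rose by 1.26 ± 0.073, from 35.7 ± 5.82 to 87.1 ± 6.32 CPM, and CDKN1C (p57) rose 12.5-fold by CPM ratio (5.55 to 34.7) from 6 control counts. CDKN2C (0.25 ± 0.055) rose slightly, while CDKN2A (-0.33 ± 0.045) and the ubiquitin ligase MDM2 (-0.65 ± 0.043) fell. MYC rose by 0.74 ± 0.049, the mitotic cyclin CCNB1 (-0.49 ± 0.046) and the proliferation marker MKI67 (-0.38 ± 0.058) fell, and the change of E2F1 was 0.10 ± 0.054 (adjusted p = 0.120). EP400, an ATPase of the TIP60 complex, rose by 0.27 ± 0.052, and its scaffold TRRAP changed by -0.08 ± 0.058 (adjusted p = 0.261). The H2A.Z genes H2AZ1 (0.04 ± 0.052, adjusted p = 0.533) and H2AZ2 (-0.08 ± 0.050, adjusted p = 0.200) did not pass the test with all libraries. Without control sgRNA1 replicate 2, the shallowest library, H2AZ2 (-0.12, adjusted p = 0.0270) and E2F1 (0.13, adjusted p = 0.0275) passed. E2F1 also passed with library totals alone, added later (0.0403). TRRAP passed without control sgRNA2 replicate 1 (-0.14, adjusted p = 0.0340) and without a filter (-0.10, adjusted p = 0.0465).

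Of 37 gene lists fixed before the data were examined, 36 had at least 3 measured members, and 8 were called higher and 6 lower in KO by camera with a preset correlation, which compares a list with all other genes. With the correlation estimated from these 8 libraries none of the 36 lists was called, the smallest adjusted p being 0.0982. The adjusted p from that test is given with each of the 14 lists. Of all tested genes, 40.7% were higher and 3.57% lower at a mean of 0.25 to 1 CPM, against 21.9% and 49.2% in the most abundant class. Of the 14 lists, only the neuronal one was later compared with genes of similar control counts. Among the 35 splits of the libraries into 4 and 4, 7 called at least 14 lists, the real one included. The 6 others kept 3 libraries of 1 arm together, as 16 splits do, and the 18 splits with 2 libraries of each arm on both sides called 1 to 8. Counts of members are at an adjusted p over all genes. Adjusted over the list alone they were the same, except for the 4 lists where both are given. Examples are log2 fold changes ± SE. Some example genes share at least 20% of their exonic bases with another annotated gene. On the same strand these were CYP51A1 (79.4%), ASNS (44.6%), ALDOA (42.3%), TUBB3 (35.8%), FAU (21.6%) and RRM2 (20.2%), and on the other strand ACAT2 (33.9%), WIPI1 (24.3%), FANCA (23.6%) and MCM2 (22.7%).

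Replication-dependent histone genes, which package new DNA and whose mRNAs normally end in a stem-loop instead of a poly(A) tail, rose together. Of 27 measured, 24 were higher and 0 lower, with a median log2 fold change of 2.58 (adjusted p = 2.50e-09, and adjusted p = 0.277 with an estimated correlation). H2BC12 (1.90 ± 0.052), the linker histone H1-2 (2.74 ± 0.088), H2BC5 (3.46 ± 0.13) and H4C8 (3.85 ± 0.24) were the clearest, and H1-2 went from 10.3 ± 1.15 to 70.4 ± 6.69 CPM (mean ± SD, n = 4). Summed over the list, KO libraries held 326 to 381 CPM and control libraries 66.8 to 79.9. Counts at genes of short RNAs without a poly(A) tail had a median change of -0.48 over 92 genes, 7 higher and 20 lower.

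Immediate-early genes, which answer growth factors and stress within minutes, rose in 25 of 27 cases and fell in 1, with a median of 1.72 (adjusted p = 2.50e-09, and adjusted p = 0.360 with an estimated correlation). The AP-1 subunit JUN (1.75 ± 0.067) went from 406 ± 20.8 to 1371 ± 144 CPM, FOSB rose by 4.53 ± 0.22, the phosphatase DUSP1 by 2.02 ± 0.086 and the matricellular gene CCN2 by 2.83 ± 0.12. Neuronal genes rose in 22 of 31 cases and fell in 3, with a median of 0.62 (adjusted p = 7.28e-05, and adjusted p = 0.0982 with an estimated correlation). The neuronal tubulin TUBB3 rose by 3.19 ± 0.068, from 9.35 ± 1.07 to 88.0 ± 3.59 CPM, the microtubule-associated MAP2 by 2.62 ± 0.085, the adhesion molecule L1CAM by 3.35 ± 0.22 and the intermediate filament INA by 2.21 ± 0.17. Autophagy and lysosome genes rose in 33 of 44 cases and fell in 3, with a median of 0.22 (adjusted p = 2.34e-05, and adjusted p = 0.0982 with an estimated correlation). MAP1LC3B, which coats autophagosomes (1.16 ± 0.053), NPC1, which exports cholesterol from lysosomes (1.03 ± 0.051), and WIPI1 (1.86 ± 0.13) were examples.

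Signalling lists with higher calls were smaller. Notch target genes rose in 8 of 12 cases and fell in 2, with a median of 0.62 (adjusted p = 0.00491, and adjusted p = 0.411 with an estimated correlation), led by the feedback inhibitor NRARP (2.25 ± 0.074) with HEY2 (1.04 ± 0.092), HES6 (0.91 ± 0.070) and the ligand JAG1 (0.84 ± 0.054). NF-kB and secreted inflammatory genes rose in 8 of 12 cases and fell in 1, with a median of 0.88 (adjusted p = 0.0197, and adjusted p = 0.362 with an estimated correlation). The cytokines CXCL8 (3.74 ± 0.34) and IL11 (2.79 ± 0.26) and the regulator NFKBIZ (1.03 ± 0.091) rose. Thinned to the smallest library, a setting added after seeing the data, the adjusted p of that list was 0.0543, and without a filter its median was 1.58. TGF-beta target genes rose in 9 of 19 cases and fell in 5, with a median of 0.26 (adjusted p = 0.0392, and adjusted p = 0.277 with an estimated correlation). Scaling by library totals alone, also added later, gave 0.0513. The median of this list was 0.10 without control sgRNA2 replicate 1, 0.44 without control sgRNA2 replicate 2 and 0.47 thinned, and it was called in each. CCN2 stands in it too, with JUNB (1.80 ± 0.088), the CDK inhibitor CDKN2B (1.48 ± 0.053) and the repressor SKI (0.83 ± 0.044). Endoplasmic reticulum chaperones rose in 11 of 20 cases (12 adjusted over the list alone) and fell in 3, with a median of 0.26 (adjusted p = 0.00906, and adjusted p = 0.364 with an estimated correlation), among them HERPUD1 (1.01 ± 0.075), the chaperone HSPA5 (0.64 ± 0.051) and SEL1L (0.63 ± 0.052) of the degradation pathway.

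Cholesterol biosynthesis genes fell in 21 of 24 cases and rose in 2, with a median of -0.54 (adjusted p = 4.62e-08, and adjusted p = 0.150 with an estimated correlation). ACAT2 (-0.91 ± 0.045), the reductase DHCR7 (-0.86 ± 0.043, from 189 ± 8.54 to 104 ± 1.54 CPM), the sterol sensor INSIG1 (-0.83 ± 0.052) and the demethylase CYP51A1 (-0.66 ± 0.042) were the clearest. MYC targets and ribosome biogenesis genes fell in 33 of 40 cases and rose in 3, with a median of -0.35 (adjusted p = 1.05e-07, and adjusted p = 0.277 with an estimated correlation). The spermidine synthase SRM (-0.67 ± 0.041), the pyrimidine synthesis enzyme CAD (-0.64 ± 0.042) and PA2G4 (-0.53 ± 0.042) fell, while MYC itself, a member of that list and of the immediate-early list, rose. G2/M and mitosis genes fell in 28 of 42 cases and rose in 5, with a median of -0.21 (adjusted p = 2.34e-05, and adjusted p = 0.362 with an estimated correlation), among them the checkpoint kinase BUB1B (-0.58 ± 0.042), the kinesin KIF20A (-0.63 ± 0.047), UBE2C (-0.67 ± 0.050) and CCNA2 (-0.52 ± 0.043).

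Falls in the more abundant housekeeping groups were small. In the most abundant class of all tested genes, 49.2% were lower and 21.9% higher, with a median log2 fold change of -0.105. Camera compares a list with genes of every abundance, and these groups were not compared with genes of matched abundance. Whether they fell more than equally abundant genes was therefore not tested. Oxidative phosphorylation genes fell in 39 of 66 cases and rose in 3, with a median of -0.15 (adjusted p = 1.54e-04, and adjusted p = 0.733 with an estimated correlation), with NDUFB10 (-0.76 ± 0.047) of complex I, ATP5F1D (-0.59 ± 0.054) of the ATP synthase and CYC1 (-0.49 ± 0.046) as examples. Cytosolic ribosomal protein genes fell in 38 of 76 cases (36 adjusted over the list alone) and rose in 4, with a median of -0.14 (adjusted p = 0.00131, and adjusted p = 0.753 with an estimated correlation), and fry, which tests whether a list moves one way on balance, gave 0.0879. RPL22 (-0.42 ± 0.046) and FAU (-0.50 ± 0.061) fell and RPL28 rose (0.31 ± 0.046). DNA replication and G1/S genes fell in 32 of 52 cases (33 adjusted over the list alone) and rose in 9, with a median of -0.16 (adjusted p = 0.00491, and adjusted p = 0.347 with an estimated correlation). UHRF1 (-0.62 ± 0.045), the helicase subunit MCM2 (-0.49 ± 0.040) and CDC45 (-0.42 ± 0.044) fell and the ribonucleotide reductase subunit RRM2 rose (0.42 ± 0.044).

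**Figure D3:**
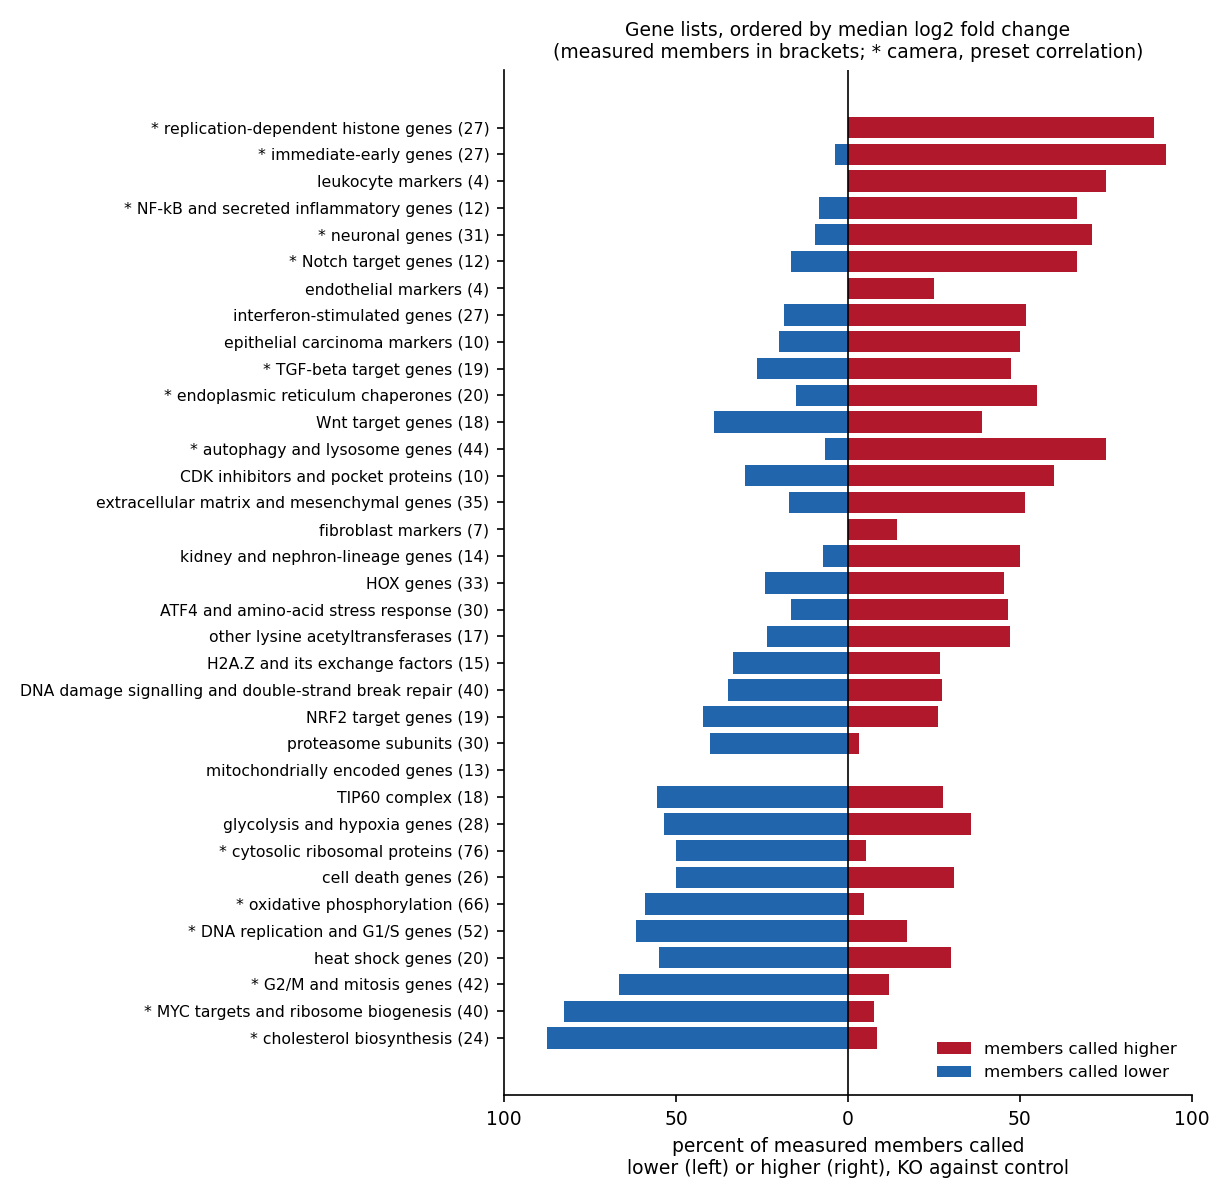
Percent of each reported list's measured members called higher (right) or lower (left) in KO, with lists ordered by median log2 fold change and an asterisk at the 14 lists called with the preset correlation. Histone genes stand at 88.9% higher and 0% lower, and cholesterol biosynthesis genes at 8.33% higher and 87.5% lower.

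Chromatin lists around TIP60 were not called by camera, although single members changed. Fry called the TIP60 complex (adjusted p = 2.37e-04) and H2A.Z and its exchange factors (0.00869) lower and HOX genes (0.00335) higher, and not the other lysine acetyltransferases (0.554). The TIP60 complex list includes KAT5, the targeted gene, and was not tested without it. Of 18 genes of the TIP60 complex, 5 rose and 10 fell (median -0.13, adjusted p = 0.178), KAT5 and the subunits MRGBP (-0.78 ± 0.071) and MEAF6 (-0.42 ± 0.052) among the falls and EPC2 (0.48 ± 0.055) among the rises. Of 17 other lysine acetyltransferases, 8 rose and 4 fell (median 0.11, adjusted p = 0.543), KAT6A rising (0.34 ± 0.046) and KAT2A falling (-0.65 ± 0.055). Of 15 genes for H2A.Z and its exchange factors, 4 rose and 5 fell (adjusted p = 0.766), including a fall of the H2A.Z chaperone ANP32E (-0.99 ± 0.045). That list's median was 0.01 (-0.03 to 0.02 with 1 library left out) while its mean was -0.04 and its test pointed down. HOX genes rose in 15 of 33 cases and fell in 8 (median 0.15, adjusted p = 0.0992). The median was 0.06 without control sgRNA1 replicate 1, 0.09 without control sgRNA2 replicate 2 and 0.07 without a filter. HOXA9 (0.88 ± 0.063) and HOXA5 (0.65 ± 0.049) were the clearest.

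Stress and damage lists held changed members in both directions, as the 14455 tested genes did (31.8% higher and 31.2% lower). None of the lists below was called by camera. Fry called CDK inhibitors and pocket proteins (adjusted p = 3.80e-04) higher and heat shock (0.0444) and NRF2 target genes (0.0186) lower. It did not call the ATF4 (0.0516), DNA damage (0.741) and cell death lists (0.652). Of 10 CDK inhibitors and pocket proteins, 6 rose and 3 fell (median 0.21, adjusted p = 0.105), CDKN2D rising by 1.42 ± 0.10. DNA damage signalling and double-strand break repair genes rose in 11 and fell in 14 of 40 cases (median -0.04, mean 0.02, adjusted p = 0.780 pointing down), H2AX (1.01 ± 0.044), XRCC4 (0.75 ± 0.070) and LIG4 (0.64 ± 0.055) rising and FANCA falling (-0.49 ± 0.049). Of 30 ATF4 and amino-acid response genes, 14 rose and 5 fell (median 0.12, adjusted p = 0.0798), with ATF3 (2.53 ± 0.12) and ASNS (0.62 ± 0.057) higher and XPOT (-0.59 ± 0.043) lower. Without KO sgRNA2 replicate 2 this list had an adjusted p of 0.00747, without control sgRNA2 replicate 2 of 0.04998 and after thinning, added later, of 0.0272. Heat shock genes rose in 6 and fell in 11 of 20 cases (median -0.16, adjusted p = 0.141), HSP90AA1 rising (0.52 ± 0.054) and FKBP4 falling (-0.69 ± 0.043). The list was called without a filter (0.0364). NRF2 target genes rose in 5 and fell in 8 of 19 cases (median -0.05, mean 0.04, adjusted p = 0.466 pointing down). HMOX1 rose (1.46 ± 0.088) and GSR fell (-0.55 ± 0.044). The median of the list was -0.03 without KO sgRNA2 replicate 1, -0.10 without KO sgRNA2 replicate 2 and -0.09 without control sgRNA1 replicate 2. Of 26 cell death genes, 8 rose and 13 fell (median -0.15, mean 0.02, adjusted p = 0.646 pointing down), PMAIP1 (1.09 ± 0.061) and CASP9 (0.99 ± 0.068) rising and BID falling (-0.87 ± 0.071).

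The remaining lists were not called by camera. Fry called interferon-stimulated (adjusted p = 1.03e-04), extracellular matrix (0.00113) and kidney genes (5.95e-04) higher and glycolysis and hypoxia genes (0.00451) and proteasome subunits (0.0284) lower. It did not call Wnt target (0.652) or mitochondrially encoded genes (0.820). By camera with an estimated correlation the adjusted p was 0.753 for proteasome subunits and 0.906 for mitochondrially encoded genes. Glycolysis and hypoxia genes rose in 10 and fell in 15 of 28 cases (median -0.14, adjusted p = 0.245), with falls of the glycolytic enzymes GPI (-0.83 ± 0.048), ALDOA (-0.76 ± 0.044) and PFKP (-0.76 ± 0.045) and a rise of KDM3A (0.72 ± 0.049). Proteasome subunits rose in 1 case (PSMD3, 0.34 ± 0.044) and fell in 12 of 30 (median -0.08, adjusted p = 0.0521), PSMB5 (-0.49 ± 0.047) among them. The proteasome list was called without a filter (0.00490), without KO sgRNA1 replicate 2 (0.0311), without KO sgRNA2 replicate 2 (0.0281), without control sgRNA1 replicate 2 (0.0145) and without control sgRNA2 replicate 1 (0.0260). Interferon-stimulated genes rose in 14 and fell in 5 of 27 cases (median 0.51, 0.32 without a filter, adjusted p = 0.0798), with OAS3 (1.67 ± 0.19) higher. Extracellular matrix and mesenchymal genes rose in 18 and fell in 6 of 35 cases (median 0.21, adjusted p = 0.0669), CCN1 rising (1.53 ± 0.094) and the basement membrane collagen COL4A1 falling (-0.99 ± 0.050). The list was called without KO sgRNA2 replicate 2 (0.0359), without control sgRNA2 replicate 1 (0.0473, median 0.32) and without a filter (0.0364). Wnt target genes rose in 7 and fell in 7 of 18 cases (median 0.25, adjusted p = 0.872), the receptor LGR5 (1.17 ± 0.051) and SOX4 (0.94 ± 0.051) rising and the cyclins CCND2 (-1.27 ± 0.069) and CCND1 (-0.87 ± 0.047) falling. Kidney and nephron-lineage genes rose in 7 and fell in 1 of 14 cases (median 0.16, and 0.69 without a filter, adjusted p = 0.147), with EYA1 (0.61 ± 0.075) higher and CDH6 at a CPM ratio of 16.1 (6.73 to 50.6; log2 fold change 3.87, and 4.55 without control sgRNA1 replicate 1). Mitochondrially encoded genes, a quality list, had 0 of 13 members called (median -0.13, adjusted p = 0.766; COX1 -0.28 ± 0.14, adjusted p = 0.0906), but without control sgRNA1 replicate 1 the median was -0.36 and the adjusted p 8.18e-05. COX1 passed there (-0.49, adjusted p = 3.58e-08) and without a filter (-0.30, adjusted p = 7.15e-16).

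Markers of cell types that a culture could hold besides HEK293 were few and gave no list called by camera. Fry called leukocyte (adjusted p = 6.06e-04) and endothelial markers (0.00409) higher and not fibroblast (0.430) or epithelial carcinoma markers (0.442). Leukocyte markers rose in 3 of 4 measured cases (median 1.26, adjusted p = 0.119), CORO1A reaching 9.71 ± 0.905 CPM from 1.99 ± 0.679 (mean ± SD, n = 4). Fibroblast markers rose in 1 of 7 cases, COL6A3 (1.05 ± 0.36), and in 0 adjusted over the list alone (median 0.16, adjusted p = 0.805), and their most abundant member FBLN1 had -0.16 ± 0.081 (adjusted p = 0.0903, and 0.0429 without control sgRNA1 replicate 1). Endothelial markers rose in 1 of 4 cases (median 0.53, adjusted p = 0.466). The median was 0.34 without KO sgRNA1 replicate 1, 0.93 without KO sgRNA2 replicate 2 and 0.35 without control sgRNA1 replicate 1. It was 0.94 without control sgRNA1 replicate 2, 1.16 without control sgRNA2 replicate 1 and 1.85 without a filter. The receptor KDR rose, at a CPM ratio of 12.8 (6.02 to 32.3; log2 fold change 3.57, and 4.23 without control sgRNA2 replicate 1). EGFL7 had -0.28 ± 0.14 (adjusted p = 0.0829, but 0.0265 without control sgRNA1 replicate 1, 0.0386 without control sgRNA2 replicate 1 and 0.0456 without a filter). Epithelial carcinoma markers rose in 5 and fell in 2 of 10 cases (median 0.31, adjusted p = 0.620), with KRT8 (0.36 ± 0.047) higher, ELF3 at a ratio of 13.9 (5.23 to 52.2) and ESRP2 (-0.97 ± 0.062) lower. TF, the 1 measured hepatocyte marker, rose by 0.87 ± 0.30, from 0.710 ± 0.169 to 1.31 ± 0.185 CPM, and that list was too small to test. With DESeq2 the adjusted p of TF was 0.0667 and that of COL6A3 0.0632. Both calls were also lost without single libraries: that of TF without control sgRNA1 replicate 1 (adjusted p = 0.114) or control sgRNA2 replicate 2 (0.0643), and that of COL6A3 without KO sgRNA1 replicate 1 (0.0645) or control sgRNA2 replicate 1 (0.0826).

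With each guide number against the controls of the same number, histone, neuronal and Notch lists were called higher and the cholesterol list lower by camera with the preset correlation. The targets of the control guides were not given, so the number alone matched KO with control libraries. NF-kB and secreted inflammatory genes were called with sgRNA1 (adjusted p = 0.00695) and not with sgRNA2 (0.0576), as were the ATF4 list (0.0199 and 0.201) and proteasome subunits (0.0351 and 0.1003). The ATF4 and proteasome lists were not called over both guides. Tested directly, the difference between the guides was not called for NF-kB genes (adjusted p = 0.0873) or proteasome subunits (0.314), and for the ATF4 list it was called (0.00622, and adjusted p = 0.703 with an estimated correlation). With an estimated correlation no list was called with a guide: adjusted p = 0.335 with sgRNA1 and 0.387 with sgRNA2 for histone genes, 0.127 and 0.125 for neuronal, 0.354 and 0.415 for Notch and 0.126 and 0.125 for cholesterol genes. TUBB3 rose by 3.19 ± 0.11 with sgRNA1 and by 3.19 ± 0.092 with sgRNA2, H1-2 by 2.88 ± 0.14 and 2.64 ± 0.12, and NRARP by 2.39 ± 0.11 and 2.13 ± 0.096, while DHCR7 changed by -0.80 ± 0.061 and -0.91 ± 0.058 (log2 ± SE, n = 2 against 2 with the spread pooled over all 8 libraries). With sgRNA1, 3515 genes were higher and 3369 lower, and with sgRNA2 3716 were higher and 3678 lower. Of these, 2930 were higher with both guides, 2884 lower with both and 1 opposite, where independent lists of these sizes would share 904, 857 and 1760. Across the 14455 genes, which are not independent replicates, the log2 fold changes of the guides had a Pearson r of 0.868 and a Spearman rho of 0.865. Called lists had medians of 2.48 and 2.44 for histone genes and of -0.49 and -0.64 for cholesterol biosynthesis with sgRNA1 and sgRNA2. A test against a fold of 1.5 called 1148 genes with sgRNA1 and 1224 with sgRNA2. Thinning to the smallest library, a setting added after seeing the data, called 4821 with sgRNA1 and 4622 with sgRNA2.

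**Figure D4:**
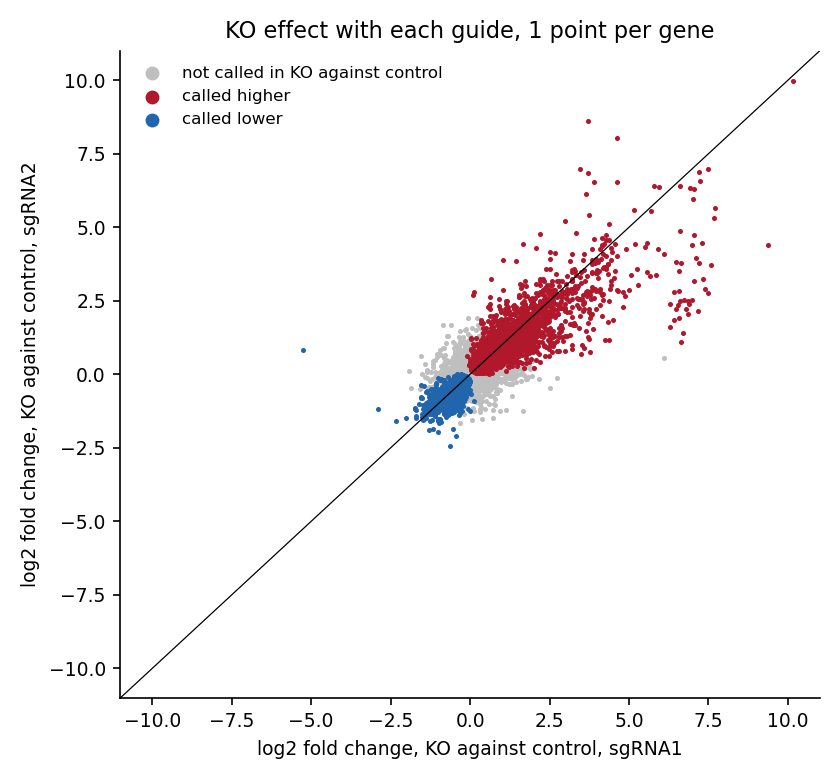
Log2 fold change of KO against control with sgRNA1 (horizontal) and sgRNA2 (vertical), 1 point per tested gene, red for genes called higher and blue for genes called lower in KO against control, with the line of equality. Of the genes called with both guides, 2930 are higher and 2884 lower with both, and the Pearson r across genes is 0.868.

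No gene had a KO effect that differed between the guides by edgeR at an adjusted p under 0.05, while 638 genes had an unadjusted p under 0.05, and DESeq2 also called 0 (192 unadjusted). The zinc finger gene ZNF681 had the smallest adjusted p, 0.198, with a change of 0.478 ± 0.086 with sgRNA1 and 1.198 ± 0.084 with sgRNA2. It was followed by SGIP1 (-5.26 ± 0.47 and 0.82 ± 0.92, adjusted p = 0.322 for the difference), the sterol carrier STARD4 (-0.22 ± 0.066 and -0.63 ± 0.062, 0.921), the imprinted gene PEG3 (1.57 ± 0.20 and 0.41 ± 0.15, 0.921) and LRATD1 (0.71 ± 0.37 and -1.22 ± 0.24, 0.921). Between the 2 KO lines 0 genes differed by edgeR, with 613 at an unadjusted p under 0.05. ZNF681, SGIP1 and LRATD1 did differ between the control lines, so their guide difference includes a difference between control libraries. With 1 library left out the count for the guide difference ranged from 0 to 25, reaching 25 without control sgRNA1 replicate 1, 23 without control sgRNA1 replicate 2 and 3 without KO sgRNA2 replicate 1. It was 11 without a filter and 1 with a replicate block. By camera with the preset correlation 9 lists differed between the guides, among them Notch target genes (adjusted p = 0.00948, and adjusted p = 0.703 with an estimated correlation) and cholesterol biosynthesis (medians -0.49 with sgRNA1 and -0.64 with sgRNA2, adjusted p = 0.00473, and adjusted p = 0.279 with an estimated correlation).

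The control lines differed in 4 genes. SGIP1 had 5.01 and 6.20 CPM in the sgRNA1 controls against 0.138 and 0.0814 in the sgRNA2 controls, a log2 difference of sgRNA2 from sgRNA1 of -5.47 ± 0.50 (adjusted p = 2.90e-05). ZNF681 (-0.85 ± 0.098, adjusted p = 4.74e-04) and the homologous recombination gene BRCA2 (-0.46 ± 0.071, adjusted p = 0.0170) were also lower and LRATD1 (1.91 ± 0.32, adjusted p = 0.0482) higher in the sgRNA2 controls. The small nuclear RNA gene RN7SK (1.80 ± 0.37, adjusted p = 0.214) and the actin cross-linker FLNC (0.49 ± 0.11, adjusted p = 0.253) came next among the higher values and did not pass. The KO libraries held 0.0584 to 0.265 CPM of SGIP1, so its KO effect of -3.73 ± 0.58 came from the sgRNA1 controls, and DESeq2 gave it -2.37 with an adjusted p of 0.0903. Without KO sgRNA1 replicate 1 the effect was -2.78 and without KO sgRNA2 replicate 2 -4.40. DESeq2 called 4 genes between the control lines, and no filter 86 (29 higher, 57 lower). Without control sgRNA1 replicate 2 the count was 116, without control sgRNA1 replicate 1 it was 63, and without KO sgRNA1 replicate 1 or 2 or control sgRNA2 replicate 1 or 2 it was 2. A stricter filter gave 2 and a test against a fold of 1.5 gave 1.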

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

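Chosen only after the results were seen were the tests of sequencing depth, of 5 other cell types and of S phase. In 322 sets of 4 values, each an examined gene or quality measure in 1 arm, 1 library far from the other 3 was looked for, and 15 were found where chance would give about 16.1, so single cases carry little weight. KO sgRNA2 replicate 2 accounted for 5 of them, and control sgRNA1 replicate 2, the shallowest library, for 3.

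KO sgRNA2 replicate 2 lay at -35.81 on the first principal component, closer to the control libraries than the other KO libraries (-42.09 to -41.30). It had the lowest KO level of JUN (1157 CPM against 1425 to 1469) and of XPOT (253.9 against 275.8 to 280.1) and the highest of RPL28 (858.2 against 758.4 to 767.7) and HOXA5 (321.3 against 289.8 to 295.1). Control sgRNA1 replicate 2 lay at 36.44 on the second component (others -16.44 to -11.35), with the lowest control CDKN2C (58.73 CPM against 73.60 to 76.27) and the highest control FANCA (159.0 against 137.4 to 139.9). KO sgRNA2 replicate 1 had the highest KO LRFN4 (17.88 CPM against 14.93 to 15.36) and the lowest ANP32E (161.1 against 182.3 to 184.3), and KO sgRNA1 replicate 2 the lowest UHRF1 (82.59 against 90.52 to 91.54). Control sgRNA2 replicate 1 had the lowest control FOSB (0.276 CPM against 0.808 to 0.895). Control sgRNA2 replicate 2 had the highest control SCRT1 (0.407 CPM against 0 to 0.0690) and was the 1 control library with a count of DUXA (0.0814 CPM) or ZSCAN4 (0.244 CPM), from 1 and 3 counts.

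The KO effect differed between the guides for 9 lists by camera with the preset correlation, at adjusted p-values from 4.65e-07 to 0.00948. Cholesterol biosynthesis had a median log2 fold change of -0.49 with sgRNA1 and -0.64 with sgRNA2 (adjusted p = 0.00473 for the difference), MYC targets and ribosome biogenesis -0.38 and -0.29 (0.00795), heat shock genes -0.22 and -0.11 (0.00860), and mitochondrially encoded genes -0.06 and -0.20 (0.00948). Other lysine acetyltransferases had 0.05 and 0.16 (0.00948), ATF4 and amino-acid stress response genes 0.17 and 0.08 (0.00622), and immediate-early genes 1.65 and 1.57 (0.00860). Notch target genes had 0.60 and 0.62 (0.00948), where the test pointed to a smaller effect with sgRNA2 although the median was slightly larger. Mitochondrially encoded genes held 2.01 to 2.16% of counts in KO and 1.29 to 2.92% in control libraries. The lowest was control sgRNA1 replicate 1, so the guide difference of that list lay mainly in the control libraries. With an estimated correlation none of the 9 differences was called, the smallest adjusted p being 0.279, and no single gene passed the same test.

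The pattern weighed first is the wider set of genes with counts and the excess of large rises in the KO libraries. Sequencing depth as the whole cause is argued against, because at equal depth the lowest KO library still had 889.5 more genes with a count than the highest control library, although thinning to the smallest library lowered the at least 2-fold rises from 1211 to 695 (with 168 falls). Reads spread evenly over genes by length are argued against only as the whole cause and by a narrow margin: among 11511 genes with 3 or fewer control counts, the top 5% held 52.4% of the KO counts against 25.6% under even spreading, a ratio of 2.048 where a bound of 2 had been set beforehand. Leukocytes, endothelial cells, hepatocytes and epithelial cells are argued against as the whole source, since cells that brought most of the rises would bring their abundant transcripts too, and the upper 95% limit of the gain of these was at most 0.751 CPM (VWF; at most 0.304 for ALB, APOA1, PTPRC, LYZ and KRT19, while EPCAM fell by 0.39, adjusted p = 9.04e-04) against a median gain of 1.91 CPM among the 1211 genes at least 2-fold higher, although other markers of these types did gain as much (CORO1A from 1.99 to 9.71 CPM, KRT8 from 81.7 to 106, KDR from 0.130 to 2.10) and all 7 transcripts too rare to test had more CPM in KO. Fibroblasts cannot be told apart from a change in the cells themselves, because COL1A1 (0.16, adjusted p = 0.215) and COL3A1 (0.21, adjusted p = 0.175) did not pass the test but already had 15.7 and 5.999 CPM in control libraries, with an upper limit of 5.757 CPM for the gain of COL1A1, and further cell types, a smaller contribution of any type or of background reads, a real opening of silent genes after loss of TIP60 and the unexplained component of the KO genotype label also stay open.

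The next pattern is the rise of replication-dependent histone transcripts. Weaker poly(A) selection in the KO libraries would have raised other RNAs without a poly(A) tail, and the 92 measured short ones had a median log2 fold change of -0.4812, below the lower quartile of the histone genes (1.93). Of these, 83 were small nucleolar RNAs, so the median speaks mainly for that class. In poly(A) libraries counts at these genes may come from longer host transcripts, so the median does not decide the question. The small nuclear RNA RN7SK went the other way (0.63), in a call lost in 7 settings. A larger share of cells in S phase would have raised replication genes, which had a median of -0.1587, with 9 of 52 higher and 32 lower. Polyadenylated histone mRNA, as seen in other cells that leave the cell cycle or differentiate, may be a candidate explanation, and it was not tested because gene counts do not show transcript ends.

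Chance as the origin of the changed genes is argued against only as far as the 35 splits of the 8 libraries into 4 and 4 allow. Of these, 1 split, the real one, gave as many as 9109 genes, a share of 0.0286 that is the smallest possible. The highest of the other splits gave 0. Splits that mix the arms put the difference between them into the spread, so their 0 calls follow in large part from the design. For the number of called lists chance cannot be excluded: the real split called 14, 7 of the 35 splits called at least as many, and the highest of the others called 18. The 6 others with at least 14 all kept 3 libraries of 1 arm together and so most of the contrast, while the 18 splits with 2 libraries of each arm on both sides called 1 to 8. The split that follows the guides called 7 lists and 0 genes.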

How the results depend on the processing

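Scaling by library totals and thinning to the smallest library were chosen after seeing the data. The 9109 genes changed between KO and control ranged from 8438 to 9322 with 1 library left out and from 8228 (DESeq2) to 9636 (no filter) under the other settings fixed in advance, except for 1616 (1216 higher, 400 lower) against a fold of 1.5, which asks for a larger change. They numbered 8942 with a replicate block, 8980 with a block by guide and replicate number, 9095 with library totals alone (5019 higher, 4076 lower) and 6637 after thinning. Of the genes called at first, 90.3% to 99.5% were called again in each setting apart from those 2 (17.7% against a fold of 1.5, 71.0% thinned), and all of these kept their direction. With sgRNA1 the count ranged from 4930 to 7026 and with sgRNA2 from 5498 to 8188 with 1 library left out. Against a fold of 1.5 it was 1148 and 1224, and after thinning, where fewer counts remain, 4821 with sgRNA1 and 4622 with sgRNA2. The guide difference gave 0 to 25 genes with 1 library left out, 11 without a filter and 1 with a replicate block. The control lines gave 2 to 116 with 1 library left out, 86 without a filter, 2 with a stricter filter and 1 against a fold of 1.5. The cause of these differences was not tested. The labels do not say whether the replicate numbers pair the samples. Deviations from the group means correlated by -0.053 to 0.028 between libraries of the same number. The highest values, 0.015 and 0.028, were those within a guide number. With 2 libraries per group, deviations hold much counting error, so these low values cannot decide the question.

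The log2 fold change of KAT5 stayed between -1.37 and -1.21. Genes called with both guides numbered 5815, 5023 at an unadjusted p under 0.01 and 4359 with DESeq2. Of 153 examined genes and 36 lists none reversed, meaning a change of direction where either fit gave a call. Values without a call did cross 0, as for H2AZ1 (-0.02 to 0.08) and the median of the DNA damage list (-0.07 to 0.01). Against a fold of 1.5, 49 examined genes lost their call. Calls were gained by H2AZ2, FBLN1, E2F1, TRRAP, EGFL7, COX1 and LRATD1, the last in 6 settings (adjusted p = 0.00499 without a filter). The call of RN7SK was lost in 7 settings, 4 of them without 1 library. Where KO sgRNA2 replicate 2 or another single library is left out, 2 libraries of a group become 1, which is then assumed to vary like the other groups. The median log2 fold change of all genes was 0.01 with TMM, 0.04 with library totals and 0.10 without a filter. Depth limits the rarest genes, since the shallowest control library held 3723992 counts.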

Other observations

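Lists written after the data were examined, and all tests of them, were chosen only after the rise of genes such as RFPL4B had been seen. Genes of the cleavage-stage embryo, including those switched on by the homeobox factor DUX4, were higher in KO libraries. Of 10 that could be tested, 9 rose and 0 fell, and the 31 genes of this list in the tables held 4303 counts in KO and 120 in control libraries (66.4 and 2.80 CPM). Most of the KO counts came from RFPL4A (1665), USP17L7 (1164) and USP17L2 (547), so the sum does not describe every member. Only 14 of the 31 genes had at least 10 counts over all libraries. Genes rare in control libraries pass the filter through their KO counts. Of all 227 tested genes under 0.25 CPM in control libraries, 227 were higher and 0 lower, so a rise of members this rare does not set the list apart. Other members, among them RFPL4A, CCNA1 and USP17L7 (0.286 CPM in control libraries), lay above that level. Of all tested genes, 47.1% were higher at 0.25 to 1 CPM in control libraries and 34.9% at 1 to 4 CPM. The 9 of 10 was not compared with genes of the same levels. RFPL4A rose by 4.48 ± 0.13 (log2 fold change ± SE, 1665 KO and 49 control counts), the meiotic cyclin CCNA1 by 3.32 ± 0.33 and the phosphate transporter SLC34A2 22.0-fold by CPM ratio (95% counting interval 7.33 to 109, from 3 control counts). The homeobox gene DUXA had 121 KO and 1 control counts (ratio 80.0, 14.1 to 3187), DUXB 47 and 2 (15.5, 4.07 to 132) and ZSCAN4, a marker of the cleavage stage, 53 and 3 (11.7, 3.79 to 58.5). Without control sgRNA2 replicate 2 the log2 fold change of DUXA was 7.67 in place of 5.84, that of ZSCAN4 6.48 in place of 3.40 and that of SLC34A2 5.23 in place of 4.26, and without control sgRNA2 replicate 1 that of ZSCAN4 was 2.82. By limma-voom DUXA had 4.77 and DUXB 2.94 (3.73 by edgeR). Counts of DUX4 itself were 2 and 0, those of TPRX1 23 and 0, and those of LEUTX 1 and 0. Most of these genes lie in multicopy or closely related families, so which copy gave the reads is uncertain.

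Other families, 9 with this list, did not share the rise evenly. USP17L genes held 1758 KO and 30 control counts (27.1 and 0.700 CPM) and RFPL genes 2531 and 166 (39.1 and 3.87). PRAMEF genes held 10 and 0, MAGEA genes 14 and 3 (0.216 and 0.070) and TRIM43, TRIM48, TRIM49 and TRIM51 genes 26 and 2 (0.401 and 0.0467). Olfactory receptor genes held 787 and 389, or 12.1 and 9.08 CPM, since the KO libraries were deeper on average. Of 4 testable germline and meiosis genes 1 rose, PIWIL2 (2.16 ± 0.37), of the piRNA pathway, and 0 fell. Genes whose names begin with DUX4, DUXA or DUXB held 1038 and 687 counts, 16.02 CPM in KO and 16.03 in control libraries, with 2 of 4 higher and 1 lower. Most of these counts came from the pseudogenes DUXAP8 (695 and 543) and DUXAP10 (173 and 141), and DUXAP8 was the 1 lower (-0.27 ± 0.11). The 2 higher were DUXA (121 and 1 counts) and DUXB (47 and 2), so the sum does not describe them. By RNA class, 257 of 804 long non-coding RNAs rose and 121 fell (median 0.18). Counts at small nucleolar RNA genes fell in 17 and rose in 4 of 83 cases (median -0.49), and those at microRNA genes fell in 11 of 29 (median -0.44). The libraries were made from poly(A) mRNA. Whether these counts came from the short RNAs themselves or from longer host transcripts was not tested.

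The hypothesis that the cleavage-stage genes only share the general rise of genes silent in control cells was tested with 10000 random lists matched on control counts. The median log2 ratio of the 14 members with at least 10 counts was 2.76, against a random median of 1.00 and an upper end of the middle 95% of random lists of 1.41, which placed it at percentile 100. Without the 3 members among the 10 largest rises, which had drawn attention to the list, the remaining 11 had a median of 2.43, also above all random lists, but counts of several of these 11 had also been looked at before the list was written, so this is not an independent test. A cleavage-stage programme that KO cells enter beyond a general rise may be a candidate explanation, but reads shared between family members and the unexplained genotype component were not excluded. The same measure gave a negative result for germline and meiosis genes (percentile 16.1) and olfactory receptor genes (percentile 11.8), and for neuronal genes it gave percentile 100 (median 0.59 against 0.12).

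Across genes, the change in KO showed little relation to GC content (Spearman rho -0.0773 over 13582 genes), exonic length (0.0534) or genomic span (0.0898) and a stronger one to mean log2 CPM (-0.240), and genes are not independent replicates.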
